A study of Caenorhabditis elegans with 2 samples.

How the data were processed

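ChIP-seq of GFP-tagged MDT-29 was performed on whole L4 larvae, in 2 samples that the labels give as biological replicates 1 and 2. Per the labels, the worms were synchronised as starved L1 larvae after bleaching, chromatin was sheared by sonication, and the assembly was ce11. The aligner and the peak caller were not given in the sources used here. Reads, an untagged strain and an input sample were not used here.

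Each deposited list gives peaks with their position, summit and 3 values made by the authors. The signal value, deposited for each peak, measures its strength, and whether it is scaled between samples is not known. The score, deposited for each peak, is a scaled form of the irreproducible discovery rate (IDR), a measure of how well a peak's rank repeats between a pair of peak lists. The ranked lists deposited by the authors also give the −log10 of the global IDR, from which the scores follow. Signal, score and IDR were used to rank, filter or describe peaks within a list. Signal was also compared between the 2 samples, by correlation, by ratio and as mean with SD, and between peaks with and without a motif. Since the scaling of signal between samples is unknown, that ratio and those SDs include any difference in scale. Per the notes deposited with the lists, the main list and the conservative list were made from the alignments of both samples, and 2 further lists from 1 sample each, with a further input whose role is not named. The thresholded lists deposited by the authors held only peaks at or above a score minimum that corresponds to a global IDR of about 0.01. Some peaks at or above that minimum in the ranked lists were taken out: 59 of 1764 in the main list, 64 of 1754 in the conservative list, 41 of 818 in replicate 1 and 58 of 1108 in replicate 2. The main and the conservative list shared 1401 peaks at identical positions (82.2% of the main list). Depth per sample is unknown, so intervals cover the counting of peaks or genes only, treat these as independent, and say nothing of variation between worms.

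Coordinates are those of ce11, which is WBcel235, with annotation release 115, and are printed counting from 1. A main peak was found in a sample when a peak of that sample's thresholded list overlapped it by at least 1 bp. For signal per sample, each main peak took the highest value among overlapping peaks of that sample's ranked list. A peak was at a promoter when its summit lay within 500 bp of the 5' end of a protein-coding transcript, and otherwise in an exon, an intron or between genes. The background for gene tests was the 19973 nuclear protein-coding genes. Gene lists (23), motifs (17), tests and the rule for named genes were fixed before the data were examined. The rule took the 25 peaks of highest signal, named by the gene with the nearest 5' end, the 4 bound members of highest signal in each list past the threshold, every bound Mediator subunit, mdt-29, and 3 members of each class past the threshold. Other genes named were chosen after their values were seen.

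Two-sided Fisher's exact tests were used for X, chromosome centres, gene lists and gene classes of at least 10 members, with exact 95% intervals. Promoters and noncoding genes (summit within 250 bp) were tested against 1000 random placements on the same chromosome, and motifs by exact McNemar tests. Correlations were tested by 100000 permutations. Their p is not given, since the peaks were chosen for ranks that repeat, possibly between the 2 samples. Benjamini-Hochberg adjustment was made within each family and 0.05 was the threshold. Shares have exact Clopper-Pearson 95% intervals. Tests ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

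The tests were tested on simulated data, 10 sets of 1705 peaks with planted effects and 10 without. Gene lists bound at 30% over a background of 3% were called in 30 of 30 cases, 60 peaks planted at tRNA genes in 10 of 10, and motifs planted in 8% of peaks in 20 of 20. Without effects, 0 of 230 list tests, 0 of 70 noncoding tests and 0 of 170 motif tests were called. In these sets motifs were searched at random positions, which lack the higher share of G and C bases of real summits. Peaks for the noncoding tests lay at random positions or near 5' ends. The counts of 0 therefore do not show how often such features of real peaks would lead to a call.

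Alternatives were the conservative list, the stronger 853 peaks, each sample alone, promoter windows of 250 and 1000 bp, other overlaps, rotations of the lists (10000), a background of 10899 named genes, each peak counted once, another motif window and control, and overlap of the noncoding gene itself. A planned global IDR of 0.01 proved to be nearly the authors' own threshold. Applied to the ranked list, without taking peaks out, it gave 1762 peaks, against 1764 at the score minimum. Chosen after seeing the data were a global IDR of 0.001 or 0.05, peaks away from small RNA genes, peaks in both lists, peaks of signal 10 or more, the 50 strongest peaks for motifs, and the correlation without the 2 strongest peaks.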

Results

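The binding of MDT-29 to the genome was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in whole Caenorhabditis elegans larvae at the L4 stage, 48 hours of age. MDT-29 is a subunit of Mediator, the coactivator complex that links DNA-bound transcription factors to RNA polymerase II. The labels name the tag in different ways, as a degron with green fluorescent protein (GFP) and as eGFP, and it was taken as a degron and GFP inserted at the mdt-29 gene. Per the labels the protein was recovered with an antibody against GFP. There was 1 group of 2 biological replicates, so no comparison between conditions was possible, and the peaks were described by where they lay. The main peak list, made by the authors from both samples, held 1705 peaks in 1699 distinct regions of the ce11 genome, with a median width of 320 bp and 523 kb covered in all. The lists made from single samples held 777 peaks for replicate 1 and 1050 for replicate 2. Read totals were not used here, so the depth of each sample is unknown, and the intervals given cover only the counting of peaks or genes.

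The strongest MDT-29 peak lay between the divergent heat shock genes F44E5.4 and F44E5.5, members of the Hsp70 family, at chromosome II 11759219 to 11759739. Its signal, a value the authors' processing gave to each peak, was 4953, against a median of 99.5 over all main peaks, and in the single samples it was 2464 ± 485 (SD, n = 2). The next peaks lay 267 bp upstream of R107.5 on chromosome III (9053849 to 9054260, signal 1969) and 549 bp upstream of F19B2.5 on chromosome V (20164318 to 20164928, signal 1196). A peak 395 bp upstream of hsp-1, the constitutive Hsp70, on chromosome IV (17278310 to 17278747) had a signal of 1098, and 534 ± 70.1 in the single samples (SD, n = 2). The 25 peaks of highest signal were named by a rule fixed before the data were examined, by the protein-coding gene with the nearest 5' end.

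Of these 25 peaks, 14 lay within 500 bp of the 5' end of a protein-coding gene and 11 were intergenic, 8 of them over 1000 bp from any such 5' end. Peaks at promoters included pck-2, which encodes phosphoenolpyruvate carboxykinase (signal 847), tent-5 (857), the co-chaperone gene dnj-13 (736), tasp-1 (700.4), the proteasome subunit gene rpn-3 (696), F17H10.1 (673), unc-23 (631), C47E8.4 (630), K08F11.1 (612), the ribosomal protein gene rpl-3 (606) and mog-4 (552). The peak named for rpn-3 also lay at the promoter of hsp-110, and that named for C47E8.4 at the promoter of hsp-90. Intergenic peaks had C30E1.4 (signal 918, 5915 bp away), srv-14 (721, 1845 bp), fbxa-190 (646, 3238 bp), Y41E3.13 (624, 1057 bp), Y105E8B.9 (590, 4073 bp), cmd-1 (590, 4758 bp) and aakg-3 (564, 4815 bp) as their nearest protein-coding genes. The intergenic peaks nearest to ins-13 (698), ZK1248.17 (689) and egg-5 (645) lay at spliced leader RNA genes of the sls-2 family, named sls-2.2, sls-2.1 and sls-2.4. The peak nearest to cmd-1 lay at the long noncoding RNA gene linc-128. The 25 peaks included 6 at promoters of genes in the list of heat shock genes and chaperones.

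How far the 2 samples gave the same peaks was asked of the single-sample lists. Strong peaks were in the thresholded lists of both samples and weak peaks mostly in neither list. In the far longer ranked lists, 1675 of the 1705 main peaks overlapped a peak of both samples. Of the 1705 main peaks, 550 (32.3%, exact 95% interval 30.04 to 34.5%) overlapped a peak in the lists of both samples, and 578 (33.9%, 31.7 to 36.2%) overlapped none in either. The list of replicate 1 held only 777 peaks, which limits the share that could be found in both. Among the 427 peaks of highest signal the share found in both was 92.3% (89.3 to 94.6%), and in the next 426 it was 30.5% (26.2 to 35.1%). In the remaining groups of 426 peaks it was 1.64% (0.663 to 3.36%) and 4.46% (2.71 to 6.88%). The weakest group includes 32 peaks of signal under 10 with median values of 41.1 and 48.6 in the single samples, and 6 of its 19 peaks found in both are among them. Whether their signal is on the same scale is unknown, so their place in the order by signal is uncertain. When peaks had to overlap by 50% of both their lengths, the overall share was 25.6%. Of the peaks of replicate 1, 71.2% overlapped a peak of replicate 2, and of those of replicate 2, 52.9% overlapped a peak of replicate 1.

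**Figure D1:**
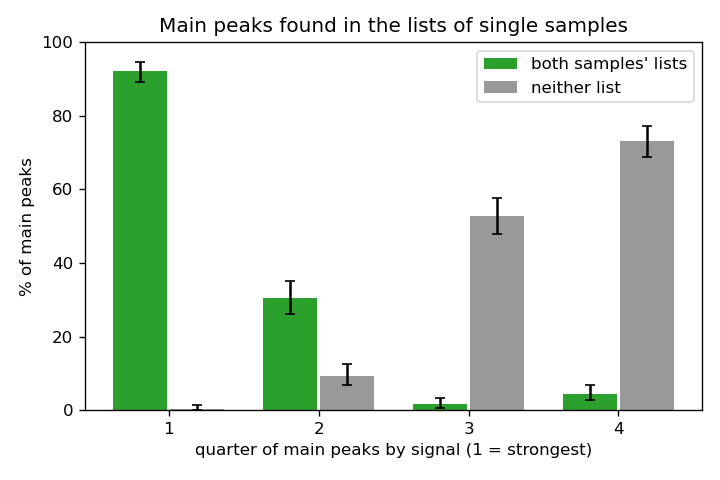
Percent of main peaks (vertical axis) that overlapped a peak in the lists of both samples (green) or in neither (grey), for main peaks ordered by signal in 4 equal groups (horizontal axis); bars give the share and lines the exact 95% interval. The share found in both was 92.3% for the strongest group and 4.46% for the weakest.

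Across the 1675 main peaks with a value in the ranked lists of both samples, peak signal correlated with Pearson's r = 0.965 and Spearman's rho = 0.549. These are correlations across peaks, which are not independent replicates. The main peaks were also chosen by the irreproducible discovery rate (IDR), a measure of how well ranks repeat between a pair of peak lists. Whether that pair stood for the 2 samples was not established here. A positive correlation may therefore be partly set by that choice, and no p is given. Without the 2 peaks of highest signal, r was 0.914 and rho 0.547. Among the 424 strongest peaks rho was 0.658, and in the 3 weaker groups it was -0.388, -0.559 and -0.333. Because the groups were cut by a signal made from both samples, values within a group are pushed toward opposite directions. The median ratio of signal in replicate 2 to replicate 1 was 1.25.

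**Figure D2:**
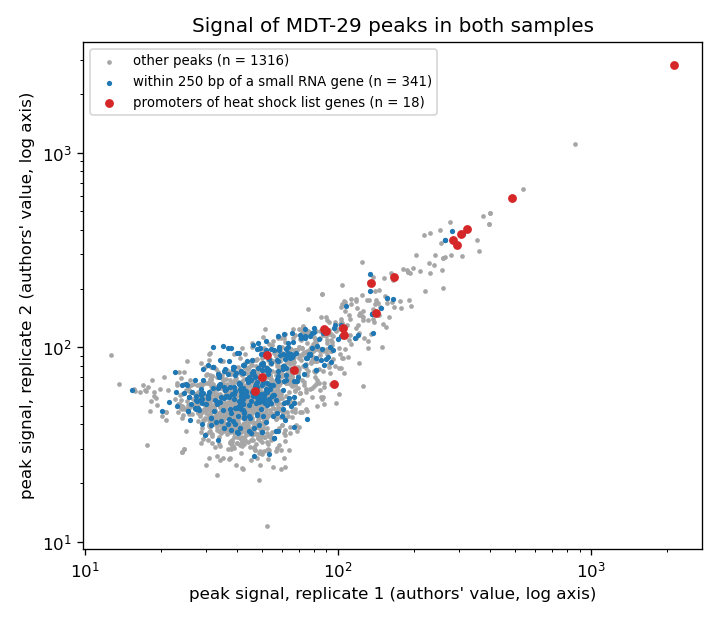
Signal of each main peak in replicate 1 (horizontal) and replicate 2 (vertical), both on log axes; each point is a peak, with peaks at promoters of heat shock list genes in red and peaks within 250 bp of a small RNA gene in blue. The peak between F44E5.4 and F44E5.5 stands at the top right, at 2122 and 2807.

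Whether MDT-29 peaks lay at promoters was tested against random placements on the same chromosomes. At promoters, within 500 bp of the 5' end of a protein-coding transcript, lay 642 peaks (37.7%, 35.3 to 40.0%). Random placements gave 22.7% ± 1.02 (SD over 1000 placements), with a highest value of 26.1% (two-sided permutation p = 0.002, the smallest possible). A further 35.3% of the main peaks were intergenic, 20.1% were in introns and 6.98% in exons. Of the promoter peaks, 73.1% (69.4 to 76.5%) lay upstream of the nearest 5' end, with a median offset of -139.5 bp. Promoter peaks marked 708 of the 19973 nuclear protein-coding genes (3.54%). The share at promoters was similar in the strongest peaks (40.7%, 36.1 to 45.6%) and the weakest (35.9%, 31.4 to 40.7%).

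Peaks were spread over all 6 nuclear chromosomes, at 12.5 per Mb on V, 16.52 on I, 17.4 on II and on IV, 19.6 on X and 20.02 on III. Without peaks within 250 bp of tRNA, snRNA, snoRNA or spliced leader genes, X had 14.1 per Mb. The other chromosomes then ranged from 10.5 on V to 16.8 on III. Of the 2731 genes on X, 2.89% had a promoter peak, against 3.65% of autosomal genes (odds ratio 0.787, 0.612 to 0.999; two-sided Fisher's exact p = 0.051). This did not pass the threshold of 0.05, but did in the authors' conservative list (odds ratio 0.764, p = 0.0287) and in the list of replicate 2 alone (0.698, p = 0.0205), while in replicate 1 alone the odds ratio was 0.998. On autosomes, 3.79% of genes in the central 50% of the chromosomes and 3.47% of those on the arms had a promoter peak (odds ratio 1.098, 0.932 to 1.30; Fisher's exact p = 0.27), a difference not detected at this number of peaks.

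Heat shock and chaperone genes and cytosolic ribosomal protein genes carried MDT-29 promoter peaks more often than other genes. Of 43 heat shock and chaperone genes 20 were bound (46.5%, against 3.45% of other genes; odds ratio 24.3, 12.595 to 46.5; Benjamini-Hochberg adjusted p = 7.75e-17 over 23 lists, Fisher's exact test). The odds ratio was 48.8 in replicate 1 alone, 37.7 in replicate 2 alone and 12.8 (12 of 43) with each peak counted once. Of 83 ribosomal protein genes in the list 21 were bound (25.3%; odds ratio 9.46, 5.45 to 15.9; adjusted p = 9.28e-12, Fisher's exact test). The list, fixed beforehand, lacked rpl-7A, which was bound as well. The strongest heat shock members, after F44E5.4 and F44E5.5, were hsp-1 and dnj-13, with single-sample signals of 534 ± 70.1 and 366 ± 58.3 (SD, n = 2). Other bound members were hsp-110, hsp-90, hsp-16.2, hsp-16.41, the endoplasmic reticulum chaperone gene hsp-3, the mitochondrial chaperone gene hsp-6, crt-1, enpl-1 and the cytosolic chaperonin genes cct-1, cct-7 and cct-8. Among ribosomal protein genes the highest single-sample signals were 299 ± 61.6 at rpl-3, 216 ± 50.1 at rpl-35, 193 ± 39.1 at rpl-15 and 183 ± 11.0 at rpl-20 (SD, n = 2). With a promoter window of 250 bp the ribosomal list no longer passed (odds ratio 3.0, adjusted p = 0.142, Fisher's exact test).

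Mitochondrial respiration and lipid metabolism genes were also bound more often than other genes. Of 46 mitochondrial respiration genes 8 were bound (17.4%; odds ratio 5.78, 2.32 to 12.64; adjusted p = 0.00109, Fisher's exact test), among them cox-5A and cox-5B of cytochrome c oxidase, atp-1 of ATP synthase and mev-1 of succinate dehydrogenase. Their single-sample signals were 157 ± 17.9, 102 ± 6.41, 81.3 ± 43.6 and 74.6 ± 21.4 (SD, n = 2). Of 53 lipid metabolism genes 9 were bound (16.98%; odds ratio 5.62, 2.40 to 11.7; adjusted p = 0.000705, Fisher's exact test), led by the desaturase gene fat-4, scp-1, the fatty acid elongase gene elo-1 and icl-1. The lipid list did not pass in replicate 2 alone (odds ratio 3.42, adjusted p = 0.137) or in the 853 main peaks of highest signal (1.95, adjusted p = 0.82), nor at a global IDR of 0.001 (1.16, adjusted p = 1; Fisher's exact test for each). Of 82 histone genes 8 were bound (9.76%; odds ratio 2.96, 1.23 to 6.18; adjusted p = 0.0392, Fisher's exact test), led by his-37 and htz-1, with his-67 and his-68 sharing a peak. The histone call was lost when the list was rotated along the gene order, which keeps neighbouring genes together (2.75 times the rotations, permutation test by 10000 rotations, adjusted p = 0.175), and in the conservative list (odds ratio 2.59, adjusted p = 0.0946). It was also lost in replicate 1 alone (1.46, adjusted p = 0.824), in the 853 stronger peaks (1.24), at a global IDR of 0.001 (1.51), with a 250 bp window (2.39) and against named genes (2.40, adjusted p = 0.0989; Fisher's exact test for each).

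**Figure D3:**
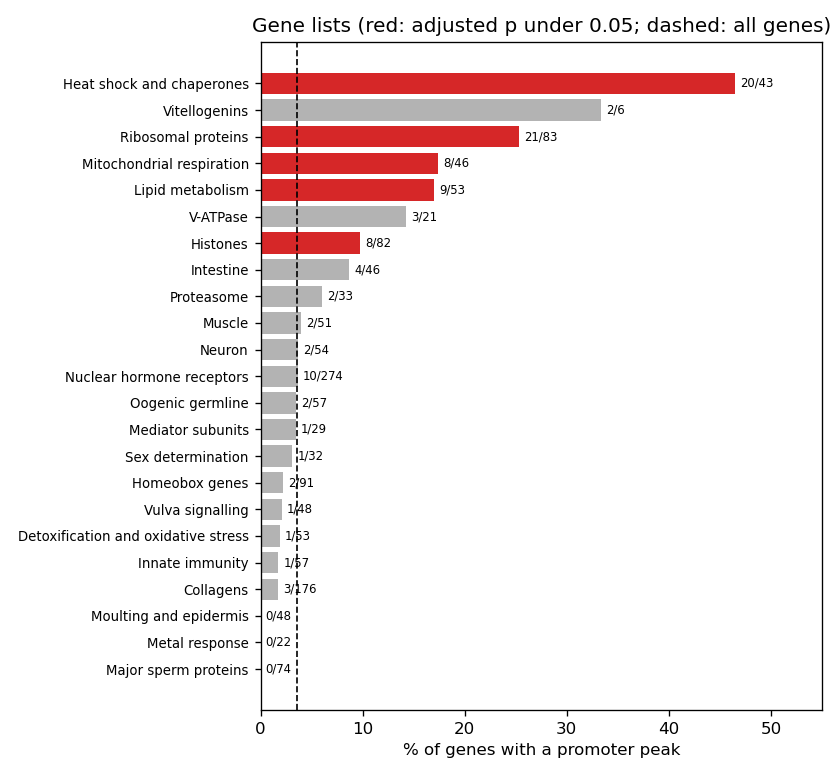
Percent of the genes of each list with a promoter peak (bars, from 0), with bound and total members beside each bar; red marks lists with an adjusted p under 0.05 and the dashed line is the share of all protein-coding genes, 3.54%. Heat shock and chaperone genes lead with 20 of 43.

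The remaining 18 lists did not pass the threshold. Of the Mediator subunits, 1 of 29 was bound, mdt-26, with a peak at chromosome II 5661073 to 5661392 (single-sample signal 59.6 ± 18.03, SD, n = 2; odds ratio 0.972, adjusted p = 1, Fisher's exact test). Of 6 vitellogenin genes, which encode yolk proteins, 2 were bound (vit-2 and vit-6; odds ratio 13.6, adjusted p = 0.0656, Fisher's exact test), and this list passed in 3 other settings, among them replicate 2 alone (20.9, exact test, adjusted p = 0.0357). Bound were 3 of 21 V-ATPase genes (odds ratio 4.55, exact test, adjusted p = 0.121, and 2.92 in replicate 1 alone), 4 of 46 intestine genes (2.60, 0.228), 2 of 33 proteasome genes (1.76, 0.685), 2 of 51 muscle genes, 2 of 54 neuron genes and 10 of 274 nuclear hormone receptor genes. Bound were also 2 of 57 oogenic germline genes, 1 of 32 sex determination genes, 2 of 91 homeobox genes, 1 of 48 vulva signalling genes, 1 of 53 detoxification and oxidative stress genes, 1 of 57 innate immunity genes and 3 of 176 collagen genes. None of 74 major sperm protein genes, 48 moulting and epidermis genes or 22 metal response genes was bound, with upper bounds of the odds ratio of 1.39, 2.17 and 4.97. The mdt-29 gene itself, on chromosome III at 13773176 to 13778908, lay 9057 bp from the nearest main peak.

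An open search over 175 gene classes, taken from the letters of the gene symbols, called 7 classes bound more often and 1 less often (Fisher's exact test, Benjamini-Hochberg adjusted). Small subunit ribosomal protein genes (rps, 11 of 31, exact test, adjusted p = 7.97e-07) were led by rps-19, rps-1 and rps-24. Heat shock genes (hsp, 8 of 22, exact test, adjusted p = 3.26e-05) were led by hsp-1, hsp-110 and hsp-90, and large subunit ribosomal protein genes (rpl, 11 of 47, adjusted p = 3.26e-05) by rpl-3, rpl-35 and rpl-15. Cyclophilin genes (cyn, 6 of 16, exact test, adjusted p = 0.000502) were led by cyn-7, cyn-10 and cyn-3. J-domain genes (dnj, 6 of 29, exact test, adjusted p = 0.0134) were led by dnj-13, dnj-12 and dnj-28. Secretory pathway genes (sec, 5 of 19, exact test, adjusted p = 0.0134) were led by sec-61.G, sec-61.B and sec-15, and bZIP transcription factor genes (zip, 4 of 12, adjusted p = 0.0154) by zip-4, zip-2 and zip-5. Of 193 str genes, which encode chemoreceptors, none was bound (exact test, adjusted p = 0.0316, upper bound of the odds ratio 0.521). The str call held in the conservative list and with a window of 1000 bp and was lost in the other 9 settings, among them each sample alone (exact test, adjusted p = 0.312 and 1). The str odds ratio was 0 in every setting, so only the adjusted p changed. The hsp class kept its call in every setting run, with odds ratios of 34.04 and 24.1 in replicates 1 and 2 alone against 15.7, while rps and rpl lost it with a window of 250 bp. The cyn call was present in neither sample alone (odds ratio 16.45 in the main list, 0 and 2.78 in replicates 1 and 2), nor in the stronger peaks (3.32) or at a global IDR of 0.001 (0). The zip call was lost in 6 of 11 settings, among them each sample alone (13.7 in the main list, 0 in both), the stronger peaks (4.53) and IDR 0.001 (5.51). The sec call was lost in 6 of 11 settings, among them replicate 2 alone (9.78 in the main list, 7.84, adjusted p = 0.206, exact test), and was 15.7 in replicate 1 alone. The dnj call was lost with both other windows (5.39 and 4.88) and with each peak counted once (5.21), against 7.15 in the main list and 12.301 in replicate 1 alone. For rpl the odds ratio was 8.43, and 14.1 in replicate 1 alone. Raised classes numbered 4 in replicate 2 alone.

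Genes of short noncoding RNAs carried many MDT-29 peaks. Within 250 bp of a tRNA gene lay 216 peaks, against 5.84 in random placements (37.01 times as many), and 240 of 612 tRNA genes had a peak. When the summit had to overlap the tRNA gene itself, peaks were 174 times as many as at random. Within 250 bp of a snoRNA gene lay 87 peaks against 3.67 at random (84 of 346 genes), and at snRNA genes other than spliced leader genes 34 against 0.964 (30 of 99 genes). Spliced leader genes, whose RNA is joined to the start of many worm messenger RNAs, had 17 peaks against 0.312 at random, at 15 of 18 sls-2 genes and 0 of 12 sls-1 genes. That is 54.5 times random, and 85.9 and 86.7 times in replicates 1 and 2 alone. It was 106 times when the summit had to overlap the gene. None of the peaks taken out of the authors' list lay at an sls-1 gene. Whether reads could be placed at sls-1 genes was not tested, so 0 of 12 does not show that MDT-29 was absent there. Peaks at miRNA genes (12 against 2.50) and long noncoding RNA genes (26 against 8.24) were also above random placements, while 0 lay at the 20 rRNA genes, where 3 peaks at rrn-4.2 were among those taken out of the authors' list. The long noncoding call was lost in replicate 2 alone (1.80 times random, permutation test, adjusted p = 0.163) and at a global IDR of 0.001 (1.81 times), against 3.16 times in the main list. The miRNA call was lost when the summit had to overlap the gene (4.72 times random, permutation test, adjusted p = 0.163) and at that IDR (3.84 times), against 4.79 times in the main list. Each of the 6 raised groups had an adjusted p of 0.00233 (permutation test, each p at 0.002, the smallest possible). In all, 353 main peaks (20.7%, 18.8 to 22.7%) lay within 250 bp of a tRNA, snRNA, snoRNA or spliced leader gene.

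**Figure D4:**
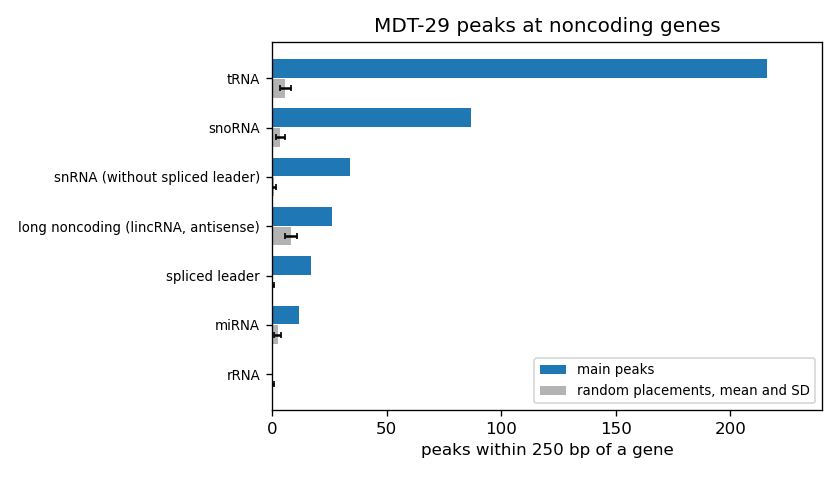
Number of main peaks within 250 bp of genes of each noncoding group (blue) and the mean of 1000 random placements with its SD (grey). The tRNA genes had 216 peaks against 5.84 at random.

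Sequences under the summits were compared with 200 bp windows centred 500 bp away. The start site motif CTGCGTCT of worm promoters was present at 7.62% of summits against 1.17% of flanks (ratio of peaks with the motif only at the summit to only in the flank 6.79, 4.18 to 11.6; adjusted p = 4.71e-20, exact McNemar test over 17 motifs). In replicate 1 alone that ratio was 15.2. The E-box CACGTG was present at 12.08% against 4.46% (ratio 3.20, 2.38 to 4.37; adjusted p = 3.99e-16, exact McNemar test), and the GC box GGGCGG at 8.80% against 3.87% (2.38). The E2F site GCGCGAAA was present at 2.23% against 0.587% (3.80), but in replicate 2 alone its ratio was 1.86 and not past the threshold (adjusted p = 0.137, exact McNemar test), while in replicate 1 alone it was 5.75. The GA repeat GAGAGAGA (ratio 2.00), the AP-1 site TGACTCA (1.95) and the nuclear receptor site AGGTCA (1.47) also passed. In replicate 2 alone the GA repeat rose to 3.53. The AP-1 site passed in neither replicate 1 alone (2.50, adjusted p = 0.0552) nor replicate 2 alone (1.09, adjusted p = 0.941), and the nuclear receptor site not in replicate 1 alone (1.22, adjusted p = 0.488; exact McNemar test for each). The AP-1 site was no more frequent than at 5' ends of genes without a peak (2.46% against 2.64%), and the nuclear receptor site missed the threshold against them (adjusted p = 0.0624, Fisher's exact test). In the conservative list neither passed (AP-1 site 1.75, adjusted p = 0.055, nuclear receptor site 1.29, adjusted p = 0.116; exact McNemar test).

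Motifs rarer at summits than in flanks were the TATA box TATAAA (ratio 0.588), the T block TTTTTTTT (0.473), the homeodomain site TAATTA (0.463), the control word TATTTAT (0.497), CCAAT (0.825) and the heat shock element TTCNNGAA (0.748). The T block was at 0.308 in replicate 1 alone, and the control word lost its call in replicate 2 alone (0.759, adjusted p = 0.179, exact McNemar test). The heat shock element was above 1 in each sample alone (1.02 and 1.12, neither past the threshold), and its call was lost in the conservative list (0.838, adjusted p = 0.111, exact McNemar test), with 100 bp windows and against 5' ends without a peak. Away from small RNA genes its ratio was 1.00, and at the 353 peaks near them 0.468. CCAAT was not called away from small RNA genes either (0.902, adjusted p = 0.324, exact McNemar test). The GATA site TGATAA (1.06), the forkhead site GTAAACA (0.957), the CRE site TGACGTCA (0.962) and the HNF4 site CAAAGTCCA (1.00) were not called. The HNF4 ratio rests on 4 peaks against 4 and was 3.0 in replicate 2 alone. Summit windows held 44.1% ± 7.10 G and C bases and flanks 36.4% ± 7.51 (SD over 1705 peaks), a difference that goes with the direction of many of these motifs.

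**Figure D5:**
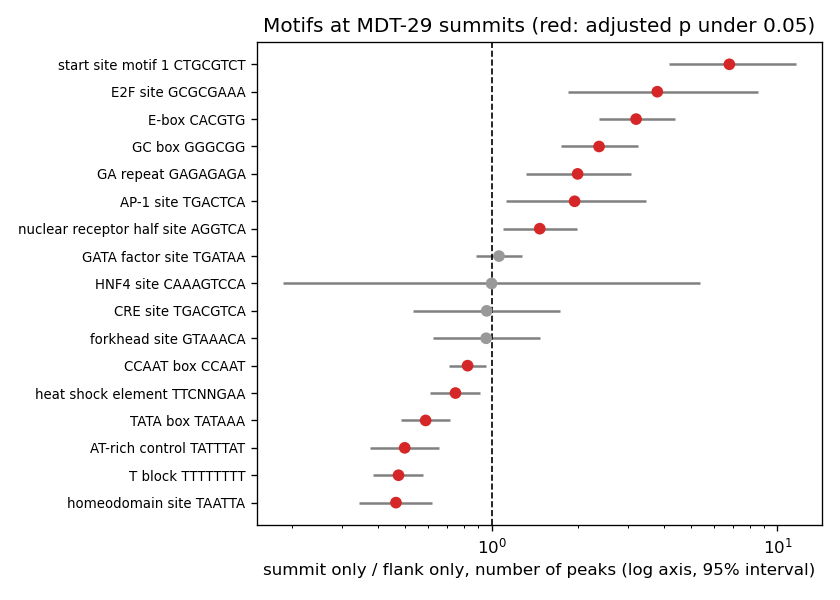
For each motif, the number of peaks with it only at the summit divided by the number with it only in the flank (points, log axis) and the 95% interval (lines); red marks an adjusted p under 0.05. The start site motif stands highest, at 6.79, and the homeodomain site lowest, at 0.463.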

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

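The tests of host promoters, of the heat shock element, of small RNA genes beside heat shock peaks, of chance positions and of single-copy against multi-copy tRNA genes were chosen only after the results they bear on were seen. The authors' thresholded list leaves out 59 peaks that pass its score in the ranked list of both samples, a signal outside the main peaks (3.34% of those passing). The strongest, at chromosome X 15810936 to 15811187, had a signal of 2606, rank 2 in the ranked list, and lay 6935 bp from the nearest coding 5' end. Their median signal was 144, 0 of the 59 lay within 500 bp of a coding 5' end, and 44 had no annotated gene within 250 bp. On chromosome V, 3 between 17122032 and 17129681 lay within 250 bp of an rRNA gene labelled rrn-4.2, and 9 others lay near each other. Further groups lay close together, among them those on chromosome I from 10946012 to 10953066 and on IV from 14779308 to 14780973. Why the 59 peaks were left out is not given in the sources used here.

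Peaks at tRNA, snRNA, snoRNA and spliced leader genes made up 20.7% of the main peaks. Of 143 tRNA genes with a sequence found once, 21.7% carried a peak, against at most 5.59% in random placements. This argues against identical tRNA copies sharing reads as the whole cause. Copies that differ by a few bases, and peaks of a repeated gene within 250 bp, were not set apart, so it does not cover them. Of the peaks at tRNA, snRNA, snoRNA and spliced leader genes, 23.2% (18.9 to 28.0%) lay within 500 bp of a coding 5' end. Host promoters are therefore argued against as the whole cause for the set. The share was not split by group and most of the peaks are at tRNA genes. It therefore cannot argue against host promoters for snoRNA genes or another single group. Shared reads may still add to the peaks of repeated genes, 44.6% of which carried one (odds ratio of single-copy against multi-copy 0.345, 0.215 to 0.541; Fisher's exact p = 5.29e-07). Unspecific recovery of highly transcribed genes stays open, since no untagged strain was analysed here, and no biological explanation was tested.

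Peaks at heat shock and chaperone genes were weighed in the same way. Neighbouring small RNA genes are argued against, since the odds ratio was 27.9 (14.5 to 53.5) without peaks near them. Double counting of peaks between neighbouring genes is argued against as the whole cause, since with each peak counted once 12 of 43 genes were bound and the odds ratio was 12.8 (5.94 to 25.7), lower than the 24.3 with all neighbours. A candidate explanation, not decided here, is a heat shock element of 3 repeats under the peaks. It was found at 7 of 18 of them and at 31 of 624 other promoter peaks (odds ratio 12.05, 3.70 to 36.9; Fisher's exact p = 2.87e-05). Promoters of the list without a peak were not searched. The comparison therefore cannot tell whether the element goes with the peaks or with the genes of the list. The remaining 11 had no such element, and unspecific recovery of active promoters stays open. It stays open for the ribosomal, mitochondrial respiration, lipid and histone lists too, since no untagged strain was analysed here.

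Of the 852 weaker main peaks, 63.0% were in neither single-sample list. Chance positions spread evenly over the chromosomes are argued against as the whole cause. Of the weaker peaks, 50.2% lay at promoters or small RNA genes, against at most 27.6% in random placements. False peaks that gather at promoters or small RNA genes would pass this test as well, so it cannot argue against them. Fewer reads in a single sample cannot be told apart from other causes here. Of these peaks 60.7% (57.3 to 63.98%) lay within the top 5% of the ranked lists of both samples. However, peaks chosen from both samples together, or for ranks that repeat between them, may rank high in both by that choice. What share of these peaks is chance stays open, and no biological explanation was tested.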

How the results depend on the processing

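The share of peaks at promoters stayed above random placements in all settings, from 37.04 to 41.4% with the 500 bp window, and the heat shock list passed in every setting run. Of 60 alternatives for the 5 called lists 49 kept the call and 11 lost it. For the 8 called classes these numbers were 58 and 26 with 4 reversed, for the 13 called motifs 103 and 34 with 5 reversed, and for the 6 raised noncoding groups 46 and 4 with 4 reversed. Of the 18 lists not called, 167 alternatives stayed as they were, 3 passed and 46 turned to the other side of an odds ratio of 1 without passing. The cause was not tested, except where fewer peaks or removed peaks show it. Read depth is unknown. Settings chosen after seeing the data were global IDR 0.001 and 0.05, peaks away from small RNA genes, peaks in both lists, signal of 10 or more, and the 50 strongest peaks.

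The peak count was 702 at a global IDR of 0.001, 3297 at 0.05 and 777 to 1050 in single samples, and the share found in both samples was 25.6% with 50% reciprocal overlap. The odds ratio of X against autosomes passed at 0.764 in the conservative list, 0.745 away from small RNA genes and 0.780 at signal of 10 or more, and ranged from 0.698 to 0.998 in single samples. That of centres against arms was 0.928 with a 250 bp window. Called lists numbered 3 in the stronger peaks and 3 at IDR 0.001. Raised classes numbered 2 with the 250 bp window, 4 with 1000 bp, 4 at IDR 0.001 and 4 to 5 in single samples. Motifs raised in the 50 strongest peaks numbered 0. At an unadjusted p under 0.05 (exact McNemar test) there were 3, the start site motif, the E-box and the heat shock element. Their ratios were 11, 9 and 3.0, and that of the GC box was 6 (p = 0.125, exact McNemar test). These ratios were above those of all peaks, but few peaks carry each motif. Away from small RNA genes 2 noncoding groups were raised, and the ratios of the tRNA, snRNA, snoRNA and spliced leader groups were 0, as that setting removes their peaks.

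Values that turned direction are odds ratios for lists and classes and ratios for motifs. In the conservative list they were detoxification 1.08, muscle 0.551, nuclear hormone receptors 0.936, oogenic germline 1.00, proteasome 0.861, the CRE site 1.04 and the forkhead site 1.05. Away from small RNA genes they were Mediator 1.11, neuron 0.587, nuclear hormone receptors 0.936, sex determination 1.01 and CRE 1.35. At signal of 10 or more, nuclear hormone receptors gave 0.929. With the 250 bp window, Mediator gave 1.66, muscle 0, nuclear hormone receptors 0.685, oogenic germline 1.69 and V-ATPase 0. With 1000 bp, neuron gave 0.716, nuclear hormone receptors 0.927, oogenic germline 1.04 and sex determination 1.24. At IDR 0.001, cyn, intestine, muscle and neuron gave 0, detoxification 1.16, sex determination 1.95, vulva signalling 1.29, CRE 1.38 and forkhead 1.07. In the stronger peaks, Mediator gave 1.78, muscle and neuron 0, sex determination 1.60 and vulva signalling 1.06. In peaks of both lists, Mediator gave 1.16, muscle 0.646, sex determination 1.04, CRE 1.22 and forkhead 1.09. Against named genes, muscle gave 0.897, neuron 0.845 and nuclear hormone receptors 0.830. Against 5' ends without a peak, AP-1 gave 0.933, CRE 1.62, GATA 0.900 and forkhead 1.095. In the 50 strongest peaks, CCAAT gave 1.11, GATA 0.429 and the heat shock element 3.0.

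In single samples the ranges were 0 to 2.78 for cyn, 0 in both for zip and neuron, 0.799 to 1.12 for detoxification, 0.924 to 2.66 for intestine, 0 to 1.49 for Mediator, 0 to 0.831 for muscle, 1.34 to 1.88 for sex determination and 0 to 1.24 for vulva signalling. For motifs they were 1.60 to 1.62 for CRE, 0.643 to 1.12 for forkhead, 1.02 to 1.12 for the heat shock element and 1.00 to 3.0 for HNF4.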

Other observations

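The tests in this part were chosen only after the results were seen. Among the 1352 main peaks away from small RNA genes, the E-box CACGTG was present at 10.2% of promoter peaks and 17.6% of other peaks (odds ratio 0.533, 0.376 to 0.747; adjusted p = 0.000784, Fisher's exact test over 5 motifs). The start site motif CTGCGTCT was present at 10.4% and 7.83% (odds ratio 1.36, 0.917 to 2.02; adjusted p = 0.301, Fisher's exact test). Peaks with an E-box had a median signal of 109 against 94.7 without, and peaks with the start site motif 117 against 95.2 (permutation test, adjusted p = 0.000375 and 5e-05). At the 353 peaks near small RNA genes the E-box was present at 2.83% of summits and 3.97% of flanks, while the GC box GGGCGG was present at 12.5% and 3.97%. The heat shock element TTCNNGAA was present at 42% of the 50 strongest peaks and 18% of their flanks (adjusted p = 0.077, exact McNemar test).

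Since summits held more G and C bases than flanks, 15 of the 17 motifs were also searched written backwards, which keeps their bases. The T block and the control word TATTTAT read the same backwards. The backward E-box GTGCAC was present at 3.28% of summits and 2.64% of flanks (ratio 1.25, adjusted p = 0.368, exact McNemar test), against a ratio of 3.20 for CACGTG. The backward TATA box was lowered further (0.413), as was the backward heat shock element (0.506 against 0.748). The backward homeodomain word ATTAAT was lowered about as much as the forward one (0.514 against 0.463, adjusted p = 6.16e-07, exact McNemar test). Other backward words went the other way from the forward ones: the nuclear receptor site (0.676 against 1.47, adjusted p = 0.00662), CCAAT (1.27 against 0.825, adjusted p = 0.0104; exact McNemar tests) and, not past the threshold, the AP-1 site (0.905 against 1.95), the GATA site (0.829 against 1.06) and the CRE site (8 peaks against 1, forward ratio 0.962). The forkhead (0.836) and HNF4 (0.429) words were not called either way. The backward GC box (2.94), E2F site (3.50), GA repeat (2.03) and start site motif TCTGCGTC (6.81) were raised too, but share 5, 5, 7 and 7 bases in a row with the forward words and are no separate controls. The backward AP-1 site also shares 5, and the backward homeodomain word 4.

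Of the tRNA genes on X, 107 of 276 had a peak (38.8%), against 23.1% of 78 on V and 50.9% of 57 on II. A total of 32 main peaks had a signal under 10, the lowest 2.09, although their median values in the single samples were 41.1 and 48.6, and 15 of them lay at promoters.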
